A study of Homo sapiens with 6 samples.

How the data were processed

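RNA-seq of RPMI-8402 T-ALL cells covered 6 libraries, 3 with doxycycline and 3 with DMSO for 72 h. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, libraries were strand-specific and sequenced as paired 100 bp reads on a DNBSEQ instrument. Per the submitters' processing notes, the authors aligned reads with STAR 2.5.2a to hg19, counted them with featureCounts and tested genes with DESeq2 1.12.4. The annotation, the featureCounts version and its strand and multi-mapping settings, the guide sequence and its target exon were not given in the sources used here. Reads shared between near-identical or overlapping genes could therefore be split or dropped in unknown ways.

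The deposited count table held whole-number counts per gene in 65913 rows, of which 2236 had a locus identifier in place of an Ensembl gene identifier and held 0.354% to 0.472% of each library's counts. The authors' deposited table of their own comparison gave, per the file headers, a mean normalized signal, a log2 fold change with its standard error on the log2 scale, a test score (the fold change over its error) and raw and adjusted p-values. Gene symbols came from that table, which paired 63677 identifiers with a symbol. The reference annotation at hand was of GRCh38, another build, so no coordinates were printed, and it served only for the chromosome of MYCN and, by gene identifier, for the length and GC content of each gene's longest transcript. These were found for 91.9% of tested genes.

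Total counts ran from 28540223 to 32203675 per library, and CPM are counts divided by these totals after scaling. Every pair of libraries within a group differed by more than counting noise (chi-square per degree of freedom 593.6, 503.0 and 50.8 among DMSO libraries and 3.44, 1.48 and 3.50 among doxycycline libraries), so all 6 were kept as separate replicates.

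The main test was edgeR 4.0.16 (R 4.3.3): genes were filtered with filterByExpr, scaled with TMM and tested with glmQLFit and glmQLFTest, doxycycline over DMSO, with Benjamini-Hochberg adjustment and a threshold of 0.05. Groups were the only factor. CPM values were divided by TMM-scaled library totals of all 6 libraries, and means are given ± SD over the 3 libraries of a group. Standard errors (SE) of log2 fold changes were calculated as the size of the change divided by the square root of its quasi-likelihood F statistic. They therefore carry no information beyond the change and its p-value. The replicate numbers were not used as a block in the main test, because same-numbered libraries did not deviate together in every pair. The outlying DMSO library described with the results can dominate deviations within its group. This check therefore could not decide whether the libraries were paired.

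Before the data were examined, 27 gene lists, the named-gene rule, the tests and the alternative settings named first below were fixed. Of the lists, 18 are described with the results and 9 (chaperones, fatty acid synthesis, lysosome and autophagy, immediate early genes, histones and markers of B, myeloid, erythroid or megakaryocytic and natural killer cells) with the additional observations. Lists with at least 3 measured members were tested against all other tested genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, with adjustment over all lists tested (26 with all 6 libraries and 27 without DMSO library 1). An estimated correlation and fry were alternatives. Of the 10 lists camera called with all 6 libraries and the 9 it called without DMSO library 1, 0 held with an estimated correlation.

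The named genes were MYCN, up to 6 genes with the largest rise and 6 with the largest fall among those past the threshold with an average log2 CPM of at least 1 and no overlap between groups, and for each list the 2 members with the smallest p among those that passed. Where no member passed, the 2 most abundant members were given as values, and every passing MYC network member was named. Some genes the rule selected are not reported here. The rule was applied again to the fit without DMSO library 1, a step added after the data had been seen.

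The alternatives fixed in advance were RLE scaling, library size only, no filter, a mean count of at least 50, DESeq2 1.42.0, limma voom, a replicate block and omission of each library in turn. Alternatives added after seeing the data were voom with sample weights, per-library lowess offsets (span 0.2) fitted on transcript GC content and length, and combinations of these or of DESeq2 with the omission of DMSO library 1. Log ratios in the GC check used a pseudocount of 1 and genes with a mean count of at least 50.

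The test was checked on simulated counts drawn from the real means, with 200 genes changed. With all 6 libraries (16469 genes), edgeR found 0% of changes of 1 log2 unit and 42% of changes of 2, with 3 false calls. DESeq2 found 15% and 88% on the same counts, with 69 false calls, and voom 0% and 46%, with 4. Without DMSO library 1 (17080 genes) edgeR found 91% and 100%, with 16 false calls. These simulations gave both groups the same spread, taken from the edgeR fit itself. In the data DMSO libraries 2 and 3 differed more than the doxycycline libraries, so the false calls do not measure the error rate there. With a GC bias put into a single library, the lowess offsets raised the recovery from 0% and 55% (16473 genes) to 100% and 100% (15155 genes). That case was easier than the data, with a smooth GC trend and a spread set below that of the real libraries. Their biological coefficient of variation was 0.257 after the correction with all 6 libraries, so this recovery does not carry over.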

Results

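RPMI-8402 is a human cell line derived from T-cell acute lymphoblastic leukaemia (T-ALL). The cells expressed Cas9 together with a doxycycline-inducible guide RNA against MYCN, which encodes a MYC-family transcription factor. Cultures received doxycycline, which switches the guide on, or DMSO as the vehicle control, and total RNA was taken after 72 h. The data comprised 6 strand-specific RNA-seq libraries, 3 with doxycycline and 3 with DMSO, with between 28540223 and 32203675 gene counts each. All 6 carried the same MYCN knockout genotype label, so the contrast was between an induced and an uninduced guide. Doxycycline-treated cells without a MYCN guide were not analysed here. The labels did not say whether the libraries of a group came from separate cultures, so p-values measured only the spread between these libraries, which may be technical.

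The comparison asked which transcripts differed after the guide against MYCN was induced. MYCN mRNA itself (ENSG00000134323, chromosome 2) lay at 98.85, 94.26 and 90.94 CPM (counts scaled to a common library total) in DMSO libraries 1, 2 and 3 and at 88.86, 92.91 and 88.70 CPM in the doxycycline libraries. Transcripts for glucose uptake and glycolysis and for cholesterol synthesis were lower with doxycycline. SLC2A3, which encodes a glucose transporter, fell from 293.1 ± 6.54 to 48.45 ± 2.26 CPM (SD, n = 3 per group), and HMGCS1, which encodes HMG-CoA synthase of the cholesterol pathway, fell from 669.2 ± 50.1 to 224.7 ± 6.95 CPM. BNIP3, which encodes a mitophagy receptor, fell from 129.1 ± 7.93 to 26.2 ± 2.11 CPM, and THEMIS, a regulator of thymocyte selection, fell from 24.0 ± 7.65 to 2.81 ± 0.486 CPM. EPHA2, an ephrin receptor kinase, rose from 1.80 ± 0.257 to 11.01 ± 0.603 CPM.

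**Figure D1:**
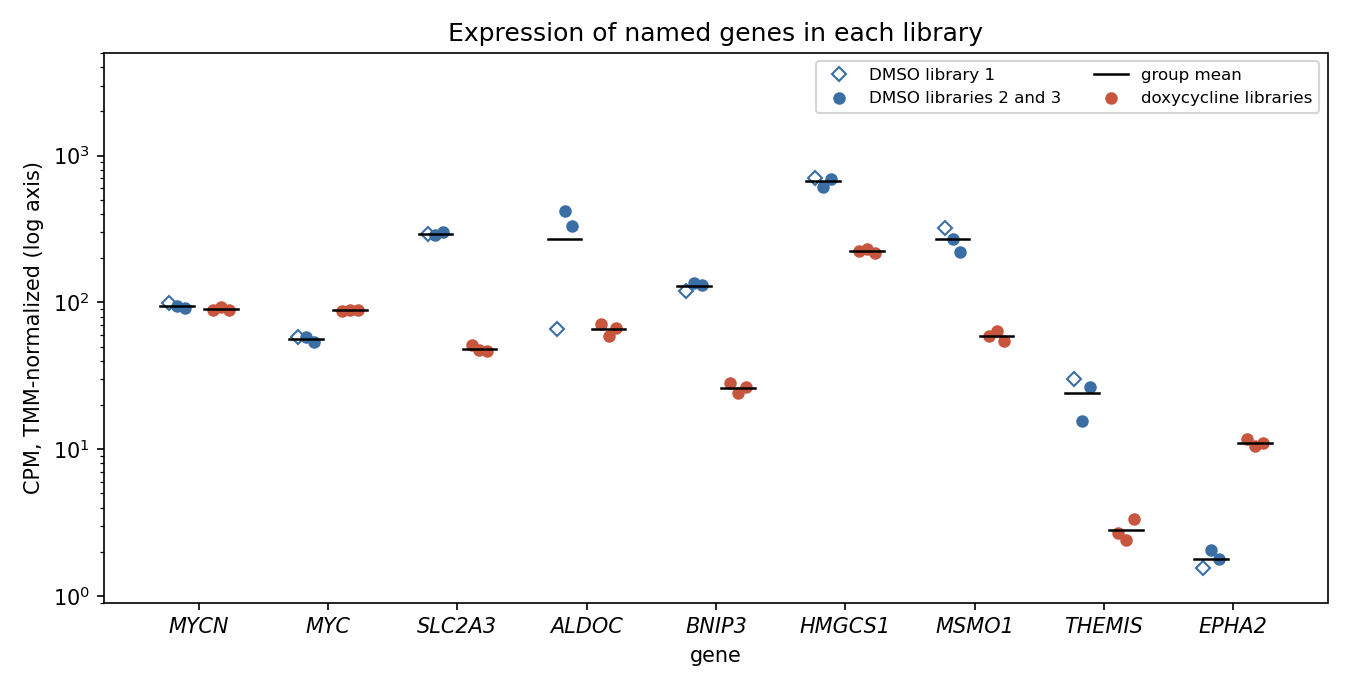
TMM-normalized CPM (log axis) of 9 genes in each library, with black bars for the group means, open diamonds for DMSO library 1, blue circles for DMSO libraries 2 and 3 and red circles for the doxycycline libraries. MYCN overlapped between the groups, SLC2A3, BNIP3, HMGCS1, MSMO1 and THEMIS were lower in every doxycycline library, and ALDOC lay at 65.64 CPM in DMSO library 1, within the doxycycline range.

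MYCN showed a log2 fold change of -0.07 (SE 0.14) and an adjusted p of 0.844 in edgeR's quasi-likelihood test of all 6 libraries. Small insertions or deletions made by Cas9 need not alter a whole-gene count, so the MYCN level checked neither the labels nor the knockout. The MYCN value was 0.239 when libraries were scaled by their size only, where the median of all genes was 0.287. It moved to -0.547 after a correction for GC content and length, and adjusted p was at least 0.457 under all 17 alternatives. The authors' deposited table gave a MYCN log2 fold change of -0.06 with an adjusted p of 0.913.

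DMSO library 1 stood apart from the other 5 libraries. Mitochondrially encoded genes held 25.2% of its counts against 6.07% to 6.73% elsewhere, and it had 23628 genes with a count against 26824 to 29622. The first principal component, with 78.8% of the variance, separated it from the rest, at a score of -153.8 against 21.4 to 34.3 for the others. Its log2 ratio to DMSO libraries 2 and 3 fell with transcript GC content, from a median of 0.99 among genes of the lowest GC bin to -1.96 in the highest (11864 genes in 8 bins). Counts of calls and list results are therefore given for all 6 libraries and again for the 3 doxycycline libraries against DMSO libraries 2 and 3, called the 5-library comparison. Single genes called in the latter have their 6-library log2 fold change beside them where the values differed by over 1.5 times. Leaving out each library in turn was fixed in advance, while the weight given to this particular omission was chosen after the library had been seen.

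**Figure D2:**
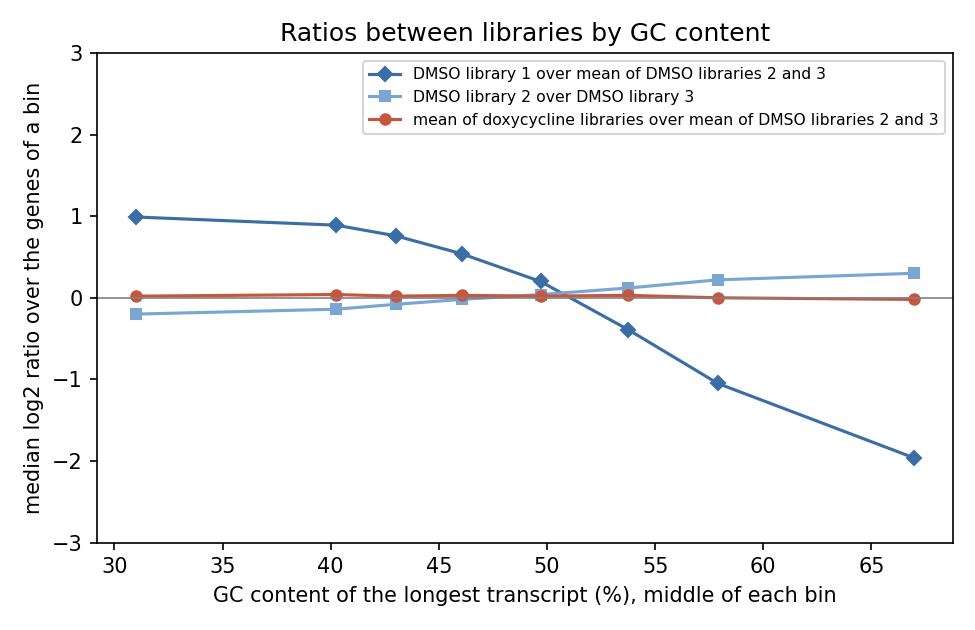
Median log2 ratio between libraries (vertical axis) over the genes of 8 bins of transcript GC content (horizontal axis, percent). DMSO library 1 over DMSO libraries 2 and 3 (dark blue diamonds) ran from 0.99 to -1.96, DMSO library 2 over 3 (light blue squares) from -0.20 to 0.30, and doxycycline over DMSO libraries 2 and 3 (red circles) stayed between -0.02 and 0.04. The last ratio had a trend with transcript length, which is not plotted (rho = 0.311).

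Among all 6 libraries, 2 genes rose and 18 fell out of 16821 tested (edgeR, adjusted p under 0.05), each by at least 2-fold. Among genes with an average log2 CPM of at least 1, the steepest falls outside the genes above were C4orf47 (log2 fold change -3.30, SE 0.30, adjusted p = 0.0277), the long noncoding RNA LY86-AS1 (-2.89, SE 0.22, adjusted p = 0.0245), NRN1, which encodes neuritin (-2.87, SE 0.29, adjusted p = 0.0348), and AK4, a mitochondrial adenylate kinase (-2.59, SE 0.25, adjusted p = 0.0348). LY86-AS1 was uncertain as an antisense transcript, because the strand setting of the counting was not given in the sources used here. SLC2A3 had the smallest adjusted p, 0.0200, at a log2 fold change of -2.60 (SE 0.15). EPHA2 had a log2 fold change of 2.61 (SE 0.22, adjusted p = 0.0260), a call that ended after the GC and length correction, where the value was 2.01 with a wider SE of 0.37 (adjusted p = 0.0694). The same correction in the 5-library comparison gave 2.47 (adjusted p = 8.45e-05). The remaining calls, listed after their values were seen, were SLCO2A1 (higher, 2.57, at 1.90 CPM with doxycycline) and ADM (-3.57, at 2.85 CPM with DMSO), P4HA1, BHLHE40, GBE1, JAM3, INSIG2, TTLL9, PPP1R3B and RP11-798M19.6 (all lower). P4HA1 encodes a collagen prolyl hydroxylase subunit, GBE1 the glycogen branching enzyme, PPP1R3B a glycogen-targeting phosphatase subunit, ADM adrenomedullin and INSIG2 a regulator of sterol synthesis.

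The 5-library comparison called 671 genes higher and 1145 lower out of 17353, of which 136 and 374 differed by at least 2-fold. DMSO libraries 2 and 3 differed more than the doxycycline libraries did (chi-square per degree of freedom 50.8 against 1.48 to 3.50). The test used a common spread per gene for both groups, so this comparison may understate the spread among DMSO libraries. All 20 genes called among the 6 libraries were called again in the same direction. Among genes with an average log2 CPM of at least 1 and no overlap between groups, the largest rises besides EPHA2 were those of BMX, a TEC-family kinase (log2 fold change 2.26, SE 0.15, adjusted p = 0.000994), MYO1F, an unconventional myosin (2.24, SE 0.21, adjusted p = 0.00283), ZNF641 (1.93), the keratin gene KRT73 (1.89) and SKIL, a repressor of TGF-beta signalling (1.85). The largest falls under the same limits were those of SFN, which encodes 14-3-3 sigma (-3.48, SE 0.25, adjusted p = 0.00109), C4orf47 (-3.15), PIK3IP1, a negative regulator of PI3-kinase (-3.15, SE 0.12, adjusted p = 0.000238), THEMIS (-2.89), LY86-AS1 (-2.83) and PFKFB4, an enzyme that sets the level of the glycolytic activator fructose-2,6-bisphosphate (-2.83, SE 0.18, adjusted p = 0.000715). Below that abundance, SLCO2A1 had a value of 2.64 and ADM -3.77. The split of calls depended on scaling. With library size alone, 1826 genes were called higher and 785 lower (69.9% higher, against 36.9% with TMM), and the median log2 fold change of all genes moved to 0.162. In the 6-library comparison the same change moved that median from -0.013 to 0.287, ended all calls in edgeR and left 2066 genes at an unadjusted p under 0.05. DESeq2 on all 6 libraries called 126 genes higher and 341 lower. When any library other than DMSO library 1 was left out, edgeR called 0 genes, with 735 to 2701 genes at an unadjusted p under 0.05.

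Glycolysis genes were lower as a group. Of 24 measured members, SLC2A3 alone passed in the 6-library comparison (10 lower and 0 higher when adjusted over the list alone), with a list median log2 fold change of -0.88. In the 5-library comparison 21 fell and none rose (23 lower adjusted over the list alone), with a median of -1.13. ALDOC, which encodes aldolase C, had a log2 fold change of -2.51 (SE 0.13, adjusted p = 0.000489), although its level in DMSO library 1 matched that of the doxycycline libraries. PFKFB4 and SLC2A3 had values of -2.83 and -2.60. The members that did not pass were PFKM (-0.19), LDHB (-0.36) and the monocarboxylate transporter gene SLC16A1 (0.08), which had 0.16, -0.05 and -0.0046 with all 6 libraries and were named after their values were seen. The competitive list test (camera) gave an adjusted p of 7.93e-11 for the 6 libraries and 3.23e-64 for the 5. These calls were lost at adjusted p = 0.472 and adjusted p = 0.0724 with an estimated correlation. After the GC and length correction the same test gave adjusted p = 0.349 for the 6 libraries and 0.022 for the 5.

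Cholesterol synthesis genes were lower too. MSMO1, a sterol methyl oxidase (log2 fold change -2.19, SE 0.20, adjusted p = 0.0277), and HMGCS1 (-1.57, SE 0.16, adjusted p = 0.0348) passed among the 6 libraries, out of 24 members measured (10 lower adjusted over the list alone). Across the 5 libraries 18 fell and 0 rose (20 lower adjusted over the list alone), with a median log2 fold change of -1.04 against -0.86 for all 6 libraries. There MSMO1 and HMGCS1 had values of -2.05 (SE 0.11) and -1.53 (SE 0.08), each at an adjusted p of 0.000517. The camera adjusted p was 8.41e-11 for the 6 libraries and 9.26e-38 for the 5. The corresponding values were adjusted p = 0.411 and adjusted p = 0.0724 with an estimated correlation, and adjusted p = 0.349 and adjusted p = 0.0198 when the GC and length correction was added. The medians of the glycolysis and cholesterol lists kept their sign when libraries were scaled by size only (-0.65 and -0.61 for all 6 libraries).

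**Figure D3:**
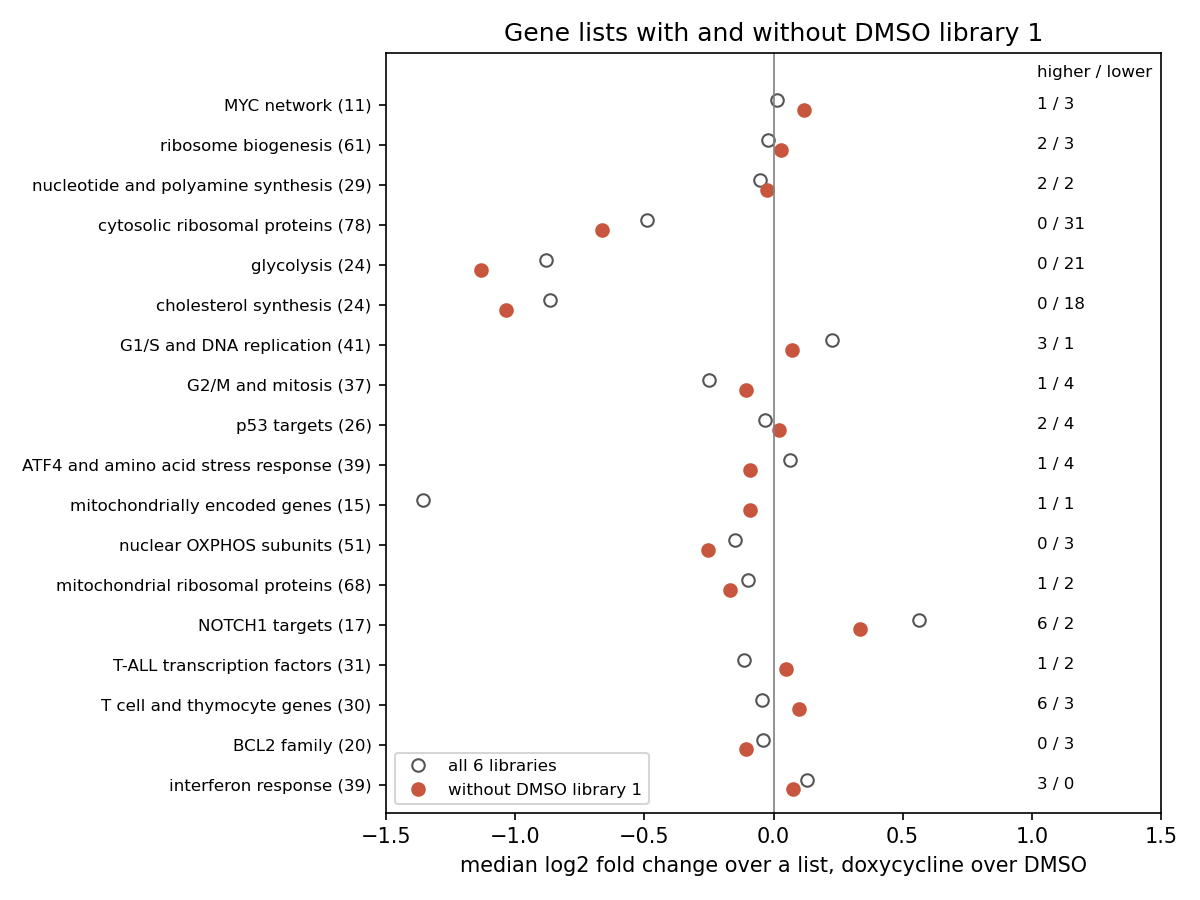
Median log2 fold change of each of 18 gene lists, doxycycline over DMSO, for all 6 libraries (open circles) and without DMSO library 1 (red circles), with the number of measured members in parentheses and, at the right, members called higher and lower without DMSO library 1. Glycolysis and cholesterol synthesis lay at -1.13 and -1.04 without that library, and the mitochondrially encoded genes moved from -1.36 to -0.09.

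Of the MYC network (11 of 12 members measured), none passed among the 6 libraries (1 higher and 1 lower adjusted over the list alone). Its most abundant members, MLXIP and MGA, had 149.8 ± 59.2 and 105.2 ± 38.2 CPM with DMSO and 200.6 ± 1.98 and 99.45 ± 4.03 CPM with doxycycline, and means of 183.9 and 87.4 CPM in DMSO libraries 2 and 3. In the 5-library comparison MYC rose from 56.0 to 88.2 CPM (log2 fold change 0.65, SE 0.075, adjusted p = 0.00581). MXI1 (-1.23, adjusted p = 0.00201), MXD1 (-0.89, adjusted p = 0.0105, and -1.72 with all 6 libraries) and MXD4 (-0.50, adjusted p = 0.0299, and -0.16 with all 6), which encode repressors that compete with MYC proteins for MAX, fell (1 higher and 3 lower adjusted over the list alone). MYC had nearly the same log2 fold change of 0.64 (SE 0.14) with all 6 libraries, at an adjusted p of 0.249. The list test gave adjusted p of 0.951 and 0.473, and its downward direction differed in sign from the list medians of 0.01 and 0.12.

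Among cytosolic ribosomal protein genes, none of 78 passed in the 6-library comparison (0 also when adjusted over the list alone), with a median log2 fold change of -0.49. RPS6 had 3926 ± 802 CPM with DMSO and 2387 ± 119 CPM with doxycycline. Across the 5 libraries 31 fell and none rose (77 lower adjusted over the list alone), at a median of -0.66, with RPL17 at -0.63 (SE 0.12, adjusted p = 0.0247) and RPL23A at -0.71 (SE 0.13, adjusted p = 0.0252). The camera adjusted p was 3.41e-11 and 4.85e-22 for the 6 and 5 libraries. The values were adjusted p = 0.472 and adjusted p = 0.653 with an estimated correlation. The median was -0.22 without DMSO library 2, and the ratio of DMSO library 2 to 3 fell with transcript length (rho = -0.581 across 11864 genes, which are not independent replicates). The ratio of doxycycline to DMSO libraries 2 and 3 rose with length (rho = 0.311), from a median of -0.18 in the shortest of 8 bins to 0.18 in the longest, and ribosomal protein transcripts had a median length of 1826 bases against 3583 for all tested genes. After the GC and length correction the medians were -0.45 with 6 libraries and -0.51 with 5 (camera adjusted p = 3.86e-10 and 4.34e-23, and adjusted p = 0.349 and adjusted p = 0.508 with an estimated correlation). These genes have many near-identical pseudogenes, so their counts were uncertain.

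Ribosome biogenesis factors and enzymes of nucleotide and polyamine synthesis showed little common direction. None of 61 biogenesis genes passed among the 6 libraries (0 adjusted over the list alone), where NPM1 had 2025 ± 246 and 1330 ± 43.5 CPM and NCL 936.2 ± 241 and 744.8 ± 18.6 CPM with DMSO and doxycycline, and DMSO libraries 2 and 3 averaged 1937 and 804.1 CPM. The 5-library comparison had 2 rises and 3 falls (1 and 2 adjusted over the list alone). MYBBP1A (0.40, and 0.79 with all 6 libraries) was among the rises, and NOB1 (-0.55) and NPM1 (-0.54, adjusted p = 0.0278) among the falls. The biogenesis list had medians of -0.02 and 0.03 and adjusted p of 0.951 and 0.713, with an upward test direction in both comparisons. Of 29 nucleotide and polyamine genes none passed among the 6 libraries (0 adjusted over the list alone), and 2 rose and 2 fell in the 5-library comparison (2 and 3 adjusted over the list alone). The purine synthesis enzymes PAICS (-0.45, adjusted p = 0.0174, and -0.89 with all 6 libraries) and IMPDH2 (-0.73, adjusted p = 0.0252) were the falls, from means of 714.2 and 701.5 CPM in DMSO libraries 2 and 3 to 523.7 ± 5.53 and 421.8 ± 13.1 CPM with doxycycline. With DMSO library 1 included, the DMSO means were 968.9 ± 442 and 600.4 ± 208 CPM. That list's adjusted p was 0.951 and 0.847.

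Cell cycle lists passed camera with all 6 libraries and not in the 5-library comparison, and after the GC and length correction neither passed with all 6 (adjusted p = 0.072 for G1/S and 0.175 for G2/M, at medians of 0.14 and -0.09). The G1/S and DNA replication list had a median of 0.23 (adjusted p = 0.0341) with all 6 libraries, where none of 41 members passed (0 adjusted over the list alone), and adjusted p = 0.733 with an estimated correlation. The median was 0.07 in the 5-library comparison (adjusted p = 0.261). There UHRF1 (0.38, and 0.69 with all 6 libraries), GINS4 and CCNE2 rose and the licensing factor CDT1 fell (-0.86, adjusted p = 0.0113, and -0.36 with all 6), with 3 and 1 also adjusted over the list alone. CCND3 and MCM7, the most abundant members, had 547.1 ± 331 and 428.3 ± 303 CPM with DMSO and 797.3 ± 29.5 and 514.2 ± 15.0 CPM with doxycycline. Their log2 fold changes moved from 0.54 and 0.26 to 0.12 and -0.22 without DMSO library 1, where the DMSO means were 731.8 and 596.9 CPM. The G2/M list had a median of -0.25 (adjusted p = 0.0228) with 0 of 37 members passing (0 adjusted over the list alone), and adjusted p = 0.472 with an estimated correlation. Its median was -0.11 in the 5-library comparison (adjusted p = 0.267). With scaling by library size only the 2 medians were 0.08 and 0.05, but -0.21 and -0.11 relative to the median of all genes. In the 5-library comparison the mitotic kinase gene TTK fell (-0.41, adjusted p = 0.0326, and -0.91 with all 6 libraries) and FOXM1 rose (0.32, adjusted p = 0.0349), among 1 rise and 4 falls (1 and 6 adjusted over the list alone). TOP2A and MKI67 had 1298 ± 249.8 and 991.3 ± 641 CPM with DMSO and 1227 ± 28.4 and 771.7 ± 24.7 CPM with doxycycline. Both turned in direction without DMSO library 1, from -0.08 and -0.36 to 0.07 and 0.30, at DMSO means of 1169 and 627.1 CPM.

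Mitochondrially encoded genes had a median log2 fold change of -1.36 with all 6 libraries (adjusted p = 0.00183, and adjusted p = 0.80 with an estimated correlation), with none of 15 passing (0 adjusted over the list alone). DMSO library 1 held a mitochondrial share of 25.2%, and the median was -0.09 without that library (adjusted p = 0.909). The call with all 6 libraries also ended after the GC and length correction (median -1.01, adjusted p = 0.072). Without DMSO library 1 MT-RNR2, the large mitochondrial ribosomal RNA, fell (-0.69, adjusted p = 0.00932) and MT-ATP8 rose (0.56, adjusted p = 0.0290), against -2.30 and -0.33 with all 6 libraries, with 1 higher and 2 lower adjusted over the list alone. MT-ATP8 overlaps MT-ATP6 and was uncertain. MT-RNR2 and MT-CO1 had 8675 and 10020 CPM as means of DMSO libraries 2 and 3, and 5388 ± 139 and 8062 ± 124 CPM with doxycycline. Nuclear OXPHOS subunits had medians of -0.15 (adjusted p = 0.0228, and adjusted p = 0.868 with an estimated correlation) and -0.25 (adjusted p = 0.00239, and adjusted p = 0.839 with an estimated correlation). The first was 0.13 with scaling by library size only, but -0.16 relative to the median of all genes. Both OXPHOS calls ended after the GC and length correction, at medians of -0.10 (adjusted p = 0.229) and -0.16 (adjusted p = 0.169). None of 51 passed among the 6 libraries (0 adjusted over the list alone), where ATP5B had 941.5 ± 138 and 889.6 ± 26.9 CPM and ATP5A1 476.7 ± 124 and 477.5 ± 17.3 CPM with DMSO and doxycycline, against means of 1006 and 534.6 CPM in DMSO libraries 2 and 3. Across the 5 libraries NDUFV2 (-1.19), CYCS, which encodes cytochrome c (-0.46), and UQCRC2 fell (1 lower adjusted over the list alone). Mitochondrial ribosomal proteins had adjusted p of 0.196 and 0.0853. Of 68, none passed among the 6 libraries, and in the 5-library comparison MRPS10 rose while MRPL17 (-0.61) and MRPL32 (-0.37, and -0.71 with all 6 libraries) fell (0 adjusted over the list alone in both). MRPL3 and MRPL37 had 226.9 ± 159 and 181.7 ± 103 CPM with DMSO and 129.2 ± 2.18 and 98.4 ± 3.11 CPM with doxycycline, and log2 fold changes that moved from -0.81 and -0.88 to -0.07 and -0.32 without DMSO library 1 (DMSO means of 135.3 and 123.1 CPM).

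NOTCH1 targets were higher as a list, at a median log2 fold change of 0.56 with all 6 libraries (adjusted p = 0.00387, and adjusted p = 0.472 with an estimated correlation) and 0.33 in the 5-library comparison (adjusted p = 0.0343, and adjusted p = 0.376 with an estimated correlation). The GC and length correction moved the former to 0.28 and ended its camera call (adjusted p = 0.0678), and left the latter at 0.33 (adjusted p = 0.0369, and adjusted p = 0.508 with an estimated correlation). None of 17 passed among the 6 libraries (2 higher and 1 lower adjusted over the list alone). In the 5-library comparison 6 rose and 2 fell (9 and 2 adjusted over the list alone), with MYC, NOTCH1 (0.69, adjusted p = 0.0410), the interleukin-7 receptor gene IL7R (1.35) and RHOU (0.33) among the rises and CD300A (-2.42, adjusted p = 0.00505) the larger fall. CD300A was of low abundance, with means of 1.74 CPM in DMSO libraries 2 and 3 and 0.321 CPM with doxycycline. NOTCH1 had 158.0 ± 68.4 CPM with DMSO and 310.5 ± 14.7 with doxycycline, and RHOU 405.1 ± 19.9 and 499.2 ± 12.5 CPM. T-ALL transcription factors had adjusted p of 0.839 and 0.412. Of 30 measured with all 6 libraries none passed (1 lower adjusted over the list alone), with TCF7 at 716.3 ± 16.4 and 1039 ± 3.37 CPM and STAT5A at 707.1 ± 253 and 1001 ± 18.0 CPM (709.1 and 846.6 CPM as means of DMSO libraries 2 and 3). Across the 5 libraries TCF7 rose (0.55, adjusted p = 0.00932) and RUNX3 (-1.08, adjusted p = 0.0117) and NKX2-1 fell (1 and 2 adjusted over the list alone).

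Of 30 T cell and thymocyte genes, THEMIS alone passed among the 6 libraries (log2 fold change -3.09, SE 0.33, adjusted p = 0.0432, with 1 higher and 1 lower adjusted over the list alone). Across the 5 libraries 6 rose and 3 fell (9 and 6 adjusted over the list alone), led by THEMIS (-2.89) and by CCR9, a chemokine receptor of thymocytes (1.36, adjusted p = 0.00209). The list test gave adjusted p of 0.839 and 0.261. In the BCL2 family, BNIP3 passed among the 6 libraries (log2 fold change -2.303, SE 0.16, adjusted p = 0.0240) out of 20 measured (2 lower adjusted over the list alone). BNIP3, BNIP3L (-1.03, adjusted p = 0.0011) and the proapoptotic gene BBC3 (-1.47, and -0.97 with all 6 libraries) fell in the 5-library comparison (4 lower adjusted over the list alone), and none rose. BNIP3 and BNIP3L are known mainly as mitophagy receptors. The BCL2 list had adjusted p of 0.268 with 6 libraries and 0.00206 with 5, and adjusted p = 0.272 with an estimated correlation in the latter.

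The p53 targets moved both ways in the 5-library comparison. Of 25 p53 targets none passed among the 6 libraries (0 adjusted over the list alone), with CCNG1 at 472.1 ± 138 and 216.6 ± 1.65 CPM and BTG2 at 90.1 ± 9.13 and 84.9 ± 2.74 CPM with DMSO and doxycycline (392.8 and 94.7 CPM as means of DMSO libraries 2 and 3). In the 5-library comparison, with 26 measured, CDKN1A, which encodes the cell cycle inhibitor p21 (-1.999, adjusted p = 0.00204), CCNG1 (-0.86, adjusted p = 0.00214), BBC3 and DDB2 fell and PLK2 and C12orf5 rose (5 higher and 7 lower adjusted over the list alone). CDKN1A was of low abundance, with means of 4.13 CPM in DMSO libraries 2 and 3 and 1.03 CPM with doxycycline. The p53 list had adjusted p of 0.951 and 0.473, and the second test pointed down at a median of 0.02. In the ATF4 and amino acid stress list none of 39 passed among the 6 libraries (1 lower adjusted over the list alone), with XPOT at 494.5 ± 267 and 361.2 ± 11.03 CPM and ATF4 at 414.1 ± 107 and 351.7 ± 7.83 CPM. XPOT turned from -0.45 to 0.08 and ATF4 went from -0.24 to -0.39 without DMSO library 1, at DMSO means of 342.4 and 459.6 CPM. Across the 5 libraries 1 rose and 4 fell (1 and 4 adjusted over the list alone), including DDIT4, an inhibitor of mTORC1 signalling (-2.40, adjusted p = 0.000155), and STC2 (-1.60, adjusted p = 0.00599), and DDIT4 had 13.8 CPM in DMSO library 1, below the 39.8 ± 1.30 CPM with doxycycline. The ATF4 list had medians of 0.06 (adjusted p = 0.951, mean -0.03) and -0.09 (adjusted p = 0.0352, and adjusted p = 0.666 with an estimated correlation). The latter had an adjusted p of 0.0959 after the GC and length correction. With scaling by library size only it was 0.07, but -0.09 relative to the median of all genes. Of 39 interferon response genes none passed among the 6 libraries (0 adjusted over the list alone), with B2M at 854.9 ± 398 and 500.2 ± 24.1 CPM and a mean of 628.7 CPM in DMSO libraries 2 and 3. XAF1 (0.68, adjusted p = 0.0141, and 0.03 with all 6 libraries, where DMSO library 1 had 80.8 CPM), CMPK2 (0.61, adjusted p = 0.0249) and OAS3 rose in the 5-library comparison (3 higher adjusted over the list alone), and the list test gave adjusted p of 0.268 and 0.261.

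The authors' deposited table listed 344 genes at an adjusted p under 0.05, 78 higher and 266 lower. Its log2 fold changes correlated with those of the 6-library comparison across 16821 genes at r = 0.966 and rho = 0.996, where genes are not independent replicates. All 20 genes called with edgeR were among its calls, and 338 of its 344 calls were called in the 5-library comparison. Both analyses used the same libraries, so this agreement was not independent support. In the authors' deposited table SLC2A3, BNIP3 and HMGCS1 were lower and EPHA2 was higher, the latter at a log2 fold change of 2.40 with an adjusted p of 8.75e-20.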

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

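The sample weights, the GC and length correction and the combinations that leave out DMSO library 1 together with another change were chosen after the data had been seen. Counts are given as higher and lower genes. With edgeR on all 6 libraries they were 2 and 18. RLE scaling gave 2 and 21, no filter 2 and 32, a mean count of at least 50 gave 1 and 22, and limma voom 1 and 19. DESeq2 gave 126 and 341. Voom with sample weights gave 358 and 872. Its weights were 0.0321, 0.31 and 1.14 for DMSO libraries 1, 2 and 3 and 3.22 to 5.5 for the doxycycline libraries. The GC and length correction gave 32 and 176. With DMSO library 1 left out as well, that correction gave 1648 and 2042 and DESeq2 866 and 1435. Library size only gave 0 and 0 in edgeR, with 2066 genes at an unadjusted p under 0.05. Leaving out each library in turn ranged from 0 to 671 higher and from 0 to 1145 lower, the top values without DMSO library 1 and 0 without each of the others (smallest adjusted p 0.0818 to 0.456). A fit with fewer libraries has fewer degrees of freedom, and the edgeR biological coefficient of variation was 0.361 with all 6 libraries and 0.113 without DMSO library 1. The causes of the other differences were not tested.

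The replicate block left 0 genes higher and 0 lower in edgeR (smallest adjusted p 0.342, 1040 genes at an unadjusted p under 0.05). Same-numbered libraries correlated in their deviations at 0.039, 0.21 and 0.038, and 2 of the 3 DMSO libraries correlated best with their own number. The outlying DMSO library can dominate deviations within its group, so these values neither established nor excluded pairing. The calls of the main test therefore rest on treating the libraries as unpaired. Camera called 10 lists under the block, as without it.

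MYCN did not pass under any of the 17 alternatives (adjusted p 0.457 to 0.979), with log2 fold changes from -0.547 to 0.239. Of the 10 named genes called among all 6 libraries, each kept its call under RLE scaling, no filter, the stricter filter, DESeq2, sample weights and without DMSO library 1, 9 did under voom (not THEMIS) and 9 under the GC and length correction (not EPHA2), and none did under library size only, the block or the omission of any other library. The folds under the settings that ended the calls included SLC2A3 at -2.30 with library size only, -2.60 under the block and -2.57 to -2.63 over the other omissions, and EPHA2 at 2.90, 2.62 and 2.58 to 2.72. The number of lists past the threshold fell from 10 to 0 with an estimated correlation, 2 with fry and 4 with the GC and length correction. With DMSO library 1 also left out it was 6 with the correction, 0 with an estimated correlation and 2 with both (glycolysis and cholesterol synthesis). Fry, which does not compare a list with other genes, went the other way. It called 11 lists without DMSO library 1, 7 with the correction and 17 with both. Without DMSO library 1 its calls included glycolysis and cholesterol synthesis (adjusted p = 0.0044 each). They also included the MYC network, G2/M and p53 lists (adjusted p = 0.0339, 0.0116 and 0.0336), which camera did not call there. Correlation with the authors' fold changes was 0.966 and moved to 0.963 with library size only, 0.588 with no filter, 0.956 with the stricter filter, 0.965 with DESeq2, 0.927 with voom and 0.959 with the block.

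Some directions reversed. PSAP was 0.12 with all 6 libraries and, with DMSO library 1 left out, -0.318 after the GC and length correction and -0.342 with DESeq2. MT-ATP8 was -0.334, ranged from -0.657 to 0.562 over the libraries left out, and was 0.839 and 0.555 in the same pair of combinations. The ATF4 list median was 0.064 and ranged from -0.093 to 0.163 over the libraries left out. The p53 list median was 0.022 under fry without DMSO library 1, where the test pointed down. The median of mitochondrially encoded genes turned to 0.173 after the GC and length correction without DMSO library 1, with the preset and with an estimated correlation. The cause was not tested. Total counts were similar in all libraries, but DMSO library 1 had a TMM factor of 0.715 against 0.965 or more elsewhere and fewer genes with a count, and genes near 1 CPM rest on few counts.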

Other observations

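The GC, label and library tests of DMSO library 1 and of the glycolysis, cholesterol and ribosomal protein genes were chosen after those results had been seen, except the tests for other blood cells and for a single DMSO library behind the ribosomal result. Fatty acid synthesis genes were lower with doxycycline. None of 17 passed with all 6 libraries (3 lower adjusted over the list alone), where SCD, the stearoyl-CoA desaturase, had 3913 ± 1343 CPM with DMSO and 1432 ± 35.3 CPM with doxycycline, and FADS2 1377 ± 578 and 1247 ± 27.5 CPM, with means of 3160 and 1706 CPM in DMSO libraries 2 and 3. Without DMSO library 1, 8 fell and none rose (10 lower and 1 higher adjusted over the list alone), led by the acetyl-CoA synthetase gene ACSS2 (log2 fold change -2.19, SE 0.11, adjusted p = 0.000412) and SCD (-1.14, SE 0.11, adjusted p = 0.00279). The list's adjusted p was 0.0129 with all 6 libraries and 1.3e-08 without DMSO library 1, and adjusted p = 0.472 and adjusted p = 0.272 with an estimated correlation. Replication-dependent histones had medians of -0.43 and -0.50 (adjusted p = 0.0104 and 0.00239, and adjusted p = 0.411 and adjusted p = 0.453 with an estimated correlation). The GC and length correction ended both camera calls, at medians of -0.34 and -0.18 (adjusted p = 0.207 and 0.183) over 13 measured members. None of 15 histone genes passed with all 6 libraries (2 lower adjusted over the list alone), with HIST1H2BK at 67.98 ± 58.4 and 24.3 ± 1.33 CPM (135.2 CPM in DMSO library 1 and a mean of 34.4 CPM in DMSO libraries 2 and 3), and 5 fell without DMSO library 1 (7 adjusted over the list alone), including HIST2H2BE (-0.98, adjusted p = 0.00505) and HIST3H2A (-1.03, adjusted p = 0.0259, and -0.50 with all 6 libraries).

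Immediate early genes moved both ways. None of 25 passed with all 6 libraries (3 higher and 2 lower adjusted over the list alone), where JUND had 224.6 ± 54.4 and 149.1 ± 7.34 CPM and IER2 54.1 ± 43.6 and 79.2 ± 2.74 CPM with DMSO and doxycycline, and means of 232.9 and 77.4 CPM in DMSO libraries 2 and 3. Without DMSO library 1, 4 rose and 5 fell (5 and 7 adjusted over the list alone), with EGR1 at 0.98 (adjusted p = 0.00273) and JUN at -0.97 (adjusted p = 0.00283), and the list's adjusted p was 0.348 and 0.909 in the 2 comparisons. Of 29 chaperone genes none passed with all 6 libraries (0 adjusted over the list alone), with HSP90AB1 at 1946 ± 220 and 1467 ± 35.2 CPM and HSPA8 at 1654 ± 432 and 1434 ± 61.1 CPM, where DMSO libraries 2 and 3 averaged 1852 and 1410 CPM. HSPA1B (-1.51, adjusted p = 0.00832), which has a near-identical copy and was uncertain, and CCT4 (-0.35, adjusted p = 0.0481, and -0.01 with all 6 libraries, where DMSO library 1 had 143.7 CPM) fell without DMSO library 1 (9 lower adjusted over the list alone), at a list adjusted p of 0.839 and 0.102. Of 31 lysosome and autophagy genes none passed with all 6 libraries (0 adjusted over the list alone), with PSAP at 874.1 ± 565 and 949.1 ± 11.8 CPM and LAMP2 at 207.3 ± 67.4 and 168.1 ± 3.97 CPM, and means of 1195 and 169.0 CPM in DMSO libraries 2 and 3. TFEB (-1.64, adjusted p = 0.0129) and ATG9A fell without DMSO library 1 (5 lower adjusted over the list alone), with list adjusted p of 0.268 and 0.909. TFEB had means of only 1.89 CPM in DMSO libraries 2 and 3 and 0.606 CPM with doxycycline.

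Markers of other blood cells gave no list call with camera. With fry, which tests whether the members move one way on balance and does not compare them with other genes, natural killer markers passed (upward, adjusted p = 0.0451 with all 6 libraries and 0.0339 without DMSO library 1), as did erythroid and megakaryocyte markers without DMSO library 1 (downward, adjusted p = 0.0339). B cell markers (9 measured, adjusted p = 0.268 and 0.916) held 0 calls with all 6 libraries (1 higher adjusted over the list alone), with BLK at 31.7 ± 18.8 and 39.7 ± 1.92 CPM and IGLL1 at 20.7 ± 14.9 and 20.6 ± 2.16 CPM, and means of 42.4 and 28.7 CPM in DMSO libraries 2 and 3. Without DMSO library 1, CD79A was called higher (1.204), with 1 higher also when adjusted over the list alone. CD79A had means of only 0.553 CPM in DMSO libraries 2 and 3 and 1.28 CPM with doxycycline. Erythroid and megakaryocyte markers (adjusted p = 0.839 and 0.267) held TFRC, the transferrin receptor, at 1440 ± 256 and 1182 ± 28.96 CPM and EPOR at 11.1 ± 3.11 and 11.1 ± 0.107 CPM (means of 1565 and 12.7 CPM in DMSO libraries 2 and 3), and TFRC fell without DMSO library 1 (-0.41, adjusted p = 0.0497, 1 lower adjusted over the list alone). Natural killer markers (adjusted p = 0.161 and 0.447) held NCAM1, which fell without DMSO library 1 (-0.82, adjusted p = 0.0488, against -1.30 with all 6 libraries, with 1 higher and 1 lower adjusted over the list alone in both comparisons), and NKG7 at 5.09 ± 3.07 and 9.62 ± 0.20 CPM (a mean of 6.63 CPM in DMSO libraries 2 and 3). Of the myeloid markers, CST3 had 4.02 ± 2.20 and 5.24 ± 0.347 CPM and ITGAM 0.968 ± 0.643 and 0.842 ± 0.0627 CPM (means of 5.13 and 1.32 CPM in DMSO libraries 2 and 3), with 0 calls in either comparison and a list adjusted p of 0.709 without DMSO library 1.

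DMSO library 1 may differ through a GC bias of the library, since its log2 ratio to the other DMSO libraries correlated with transcript GC content at rho = -0.711 across 11864 genes. Correction for GC content and length lowered the SD of that ratio from 1.39 to 0.938, still above the 0.418 between DMSO libraries 2 and 3, so this trend was not its whole difference. A doxycycline library under a wrong label was argued against: over 420 genes called without it and over 2-fold apart, its level followed that of the other DMSO libraries with a slope of 0.85 (95% bootstrap interval over genes 0.78 to 0.92), where 1 is the DMSO and 0 the doxycycline level, although only 62.6% of all 1696 called genes lay nearer to the DMSO level. RNA of other blood cells was argued against too, because the highest of 12 abundant lineage transcripts in it, NKG7, reached only 2.03 CPM, below the 5.10 and 8.16 CPM of the other DMSO libraries. RNA quality, not measured in the files used here, stays open, and no biological explanation was tested.

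The lower glycolysis and cholesterol synthesis genes were not accounted for by GC content or length, since the median log2 fold change of both lists together was -1.01 (SD over members 0.72) after that correction with all 6 libraries, nor by DMSO library 1 alone, since it was -1.09 (SD 0.68) without it. As several genes among the strongest falls respond to low oxygen, a list of other oxygen-responsive genes, none of them in the glycolysis list, was written after the strongest falls had been seen and before its own values were. Without DMSO library 1, 16 of its 23 measured members fell (69.6%, against 6.6% of all tested genes) and 0 rose, among them FAM162A (-1.83), RAB20 (-2.02) and HILPDA (-1.72), with a list p of 0.00187 with an estimated correlation, while 0 passed with all 6 libraries (median -0.63; camera p = 3.27e-08). Both list p-values were unadjusted, unlike the values given for the lists fixed in advance. They also came from different settings, an estimated correlation without DMSO library 1 and the preset correlation with that library included. The estimated correlation was not applied to this list with DMSO library 1 included. These values therefore cannot be compared with each other or with the adjusted values of the glycolysis list. None of the measured members of the oxygen list was in the cholesterol synthesis list, so the oxygen list did not address those genes. A hypothesis for the glycolysis and oxygen-responsive genes is that doxycycline cultures had a weaker response to low oxygen. Such a weaker response could follow from MYCN disruption, from culture density or from doxycycline itself, known to inhibit mitochondrial translation. These cannot be told apart here, because 0 doxycycline libraries came from cells without a MYCN guide. Doxycycline given to such cells would separate the drug from the guide, and cultures matched for density would test density; neither was analysed here.

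Lower ribosomal protein transcripts might reflect composition of single DMSO libraries as much as treatment. The trend with GC content and length was argued against as the whole cause, since the median log2 fold change was -0.45 after that correction with all 6 libraries and -0.51 without DMSO library 1, in the first case with every doxycycline library below every DMSO library. A treatment effect and a single DMSO library behind most of the difference both stay open, because the median over the 77 members with a mean count of at least 50 and a known GC content was -0.23 without DMSO library 2, against -0.67 and -0.56 without libraries 1 and 3. After correction the median deviation of these genes was 0.504 in DMSO library 2, 0.128 in DMSO library 3 and -0.008 in DMSO library 1, and -0.133 to -0.244 in the doxycycline libraries.

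For the counts of genes called, 1 of the 10 splits of the 6 libraries, the real one, gave at least 2 genes higher, and 1 of the 10 gave at least 18 lower, with 0 the highest count in either direction among the other splits. With 10 splits no share under 0.05 can be reached.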
